A study of Homo sapiens with 20 samples.

How the data were processed

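Mitochondria were isolated from K562 cells by fractionation, RNA was extracted with TRIzol, treated with CMC and made into stranded total RNA libraries, per the labels' protocols. The label of the CMC libraries gives 0.5 M CMC. The submitters' processing notes name Trimmomatic, STAR and SAMtools, without versions, and the builds GRCh38 and hg38. How variant reads were called is not given in the sources used here. The deposited values are a signed score per position, headed as a difference per the file headers, with no unit stated. The authors' file for each CMC library lists 16570 positions, from 2 to 16571, with no read count, base or separate untreated value. Values other than 0 lay between positions 16 and 16558. That these numbers are GRCh38 coordinates was assumed. The score was read as percentage points of altered reads, CMC minus untreated. The highest, 33.3, equals 1 of 3 as a percentage. All 18 pairs of libraries from one group shared identical negative values (70 to 512 positions, equal within 1e-09), and none of 73 pairs from different groups did. So 1 untreated profile appears to have been subtracted within each group. The untreated libraries entered the comparisons only through these differences.

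Of 20 samples, 14 CMC libraries carry a profile and were compared, grouped by their labels as control (4), NME6 knockout (4), RPUSD4 knockdown (3) and knockout with wild-type NME6 cDNA (3). The 6 untreated samples were not analysed here on their own. The labels list a single untreated library each for the RPUSD4 knockdown and the rescued cells, and more for the other groups. Only mitochondrial positions were read, so NME6 and RPUSD4 transcripts were not analysed here and the perturbations were not checked by them. Depth per library is unknown, so no counting interval is given.

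Positions were assigned to 37 mitochondrial genes (22 tRNAs, 13 mRNAs, 2 rRNAs) with RefSeq coordinates of GRCh38. No genome sequence was used here. The known RPUSD4 position in 16S rRNA was therefore found from the gene start and its published base number, and it coincided with the highest position of RNR2, 3067. The tRNA positions 616 (TRNF, conventional position 39) and 4447 (TRNM, conventional position 50) were found in the same way. Without bases, the planned lists of uridines became lists of all tested positions in 16S rRNA, 12S rRNA, tRNAs, mRNAs and outside genes.

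Differences between groups were tested with limma 3.58.1 in R 4.3.3 (linear fit, empirical Bayes with a mean-variance trend) on the scores as given, since they can be negative. All 14 libraries shared 1 estimate of the spread. Positions with a mean of 1 or more over all libraries were tested, 149 in all. P-values were two-sided and adjusted by Benjamini-Hochberg over these positions, with a threshold of 0.05. Exact two-sided permutation tests (scipy 1.17.1) compared group means at the 10 highest control positions and the mean of each list. There were 6 lists and 5 comparisons, so 30 list tests were adjusted together. The smallest exact p is 0.0571 for 4 against 3 libraries, which cannot reach the threshold, and 0.0286 for 4 against 4. After adjustment over the 30 list tests no list could reach it either, so the list tests show no lack of change. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used. The limma step was tested on simulated data for RPUSD4 knockdown against control with the spread of the 149 positions. Over 50 draws it recovered 93.8% of changes of 4 SD and 100% of changes of 8 SD, and 4.15% of its calls were false. The simulated values were normal and independent between positions. The data hold many exact zeros, high values in single libraries and correlated neighbours, so these shares need not hold for them.

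Groups, tests, most other settings and the rule for named positions were fixed before the data were examined. The rule named the known RPUSD4 positions, up to 10 positions each way per comparison that passed the threshold without overlap between the groups, and the 10 highest control positions. The last part was to be limited to uridines, and was taken over all bases. The conventional number of the tRNA-Leu(UUR) position was looked up after its values were seen.

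Replicate numbers in the labels are shared between groups. For NME6 knockout against control, deviations from the group means correlated between libraries of the same number at 0.471, 0.286, 0.193 and 0.116 across the tested positions. The highest correlation of each knockout library with a control library of another number was -0.340, 0.246, 0.159 and 0.121, so knockout replicate 4 matched another number slightly better than its own. Each same-number value is above 0.1, so by the rule set in advance the numbers were taken to pair these samples, a pairing that comes from the data, not from the labels. With the number as a block 0 positions passed, as without it. A sign-flip test over the 4 pairs, added after the results were seen, cannot go below an exact p of 0.125. In the other comparisons the correlations were below 0.1 or negative.

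Alternatives covered each replicate left out in turn, the block, no level filter or a mean of 5 or more (4 positions, fitted without the trend, which the script used only for 20 or more), fits on only the 2 groups compared, and reading the next position. Others were chosen after seeing the data: no variance trend, a median filter, replicate 1 of control and knockout left out together, positions outside genes left out, a signed log2 scale, library scaling and library weights. Scaling divided each library by its mean over 5904 untested positions whose mean over all libraries was 0.1 to under 1, relative to all libraries. A mean over untested positions refers below to these 5904 positions.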

Results

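Pseudouridine in mitochondrial RNA was measured by CMC sequencing in K562 cells, a human chronic myelogenous leukaemia line. CMC is a carbodiimide that stays bound to pseudouridine, and the adduct disturbs reverse transcription at that base. There were 14 CMC-treated libraries with a profile: 4 from cells with a non-targeting guide (control), 4 from NME6 knockout cells, 3 from RPUSD4 knockdown cells and 3 from NME6 knockout cells given wild-type NME6 cDNA (rescued cells). RPUSD4 is a mitochondrial pseudouridine synthase that acts on 16S rRNA, and NME6 is a mitochondrial member of the nucleoside diphosphate kinase family. Each profile held 1 signed difference per position, CMC minus untreated, for 16570 listed positions. Their numbers were taken to be mitochondrial coordinates of GRCh38. These differences are called levels here and read as percentage points, a unit inferred from the values. Read depth is unknown, and an exact 0 may mean no reads. No base sequence was used, so a tested or called position need not be a uridine. Between 27.7% and 68.2% of positions in a library were listed at 0. The untreated values appear to have been shared within each group, and the spread between replicates would then leave out their error in every comparison. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries.

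In control libraries 3 positions inside genes stood high in every library. Position 3258, base 29 of the tRNA-Leu(UUR) gene TRNL1 (3230 to 3304), had 19.7 ± 3.94 points (SD, n = 4). It is conventional tRNA position 27, which the synthase PUS1 is known to modify. Position 3067, base 1397 of the 16S rRNA gene RNR2 (1671 to 3229) and the known RPUSD4 target, had 14.7 ± 0.911 points. Position 6293, base 390 of the COX1 mRNA, which encodes a subunit of cytochrome c oxidase, had 9.001 ± 1.45 points. The other 7 of the 10 highest control positions were uneven between libraries. In TRNF (tRNA-Phe) position 588 read 33.3 points in control replicate 1 and 0 in the other 3 control libraries. Positions 1334 and 1335 of the 12S rRNA gene RNR1 reached 22.2 points in 1 control library each. TRNG (tRNA-Gly) position 10048 ranged from 1.87 to 12.1 points. Positions 308, 309 and 310 of the control region, outside genes, were negative in control replicate 1 and positive in the others.

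**Figure D1:**
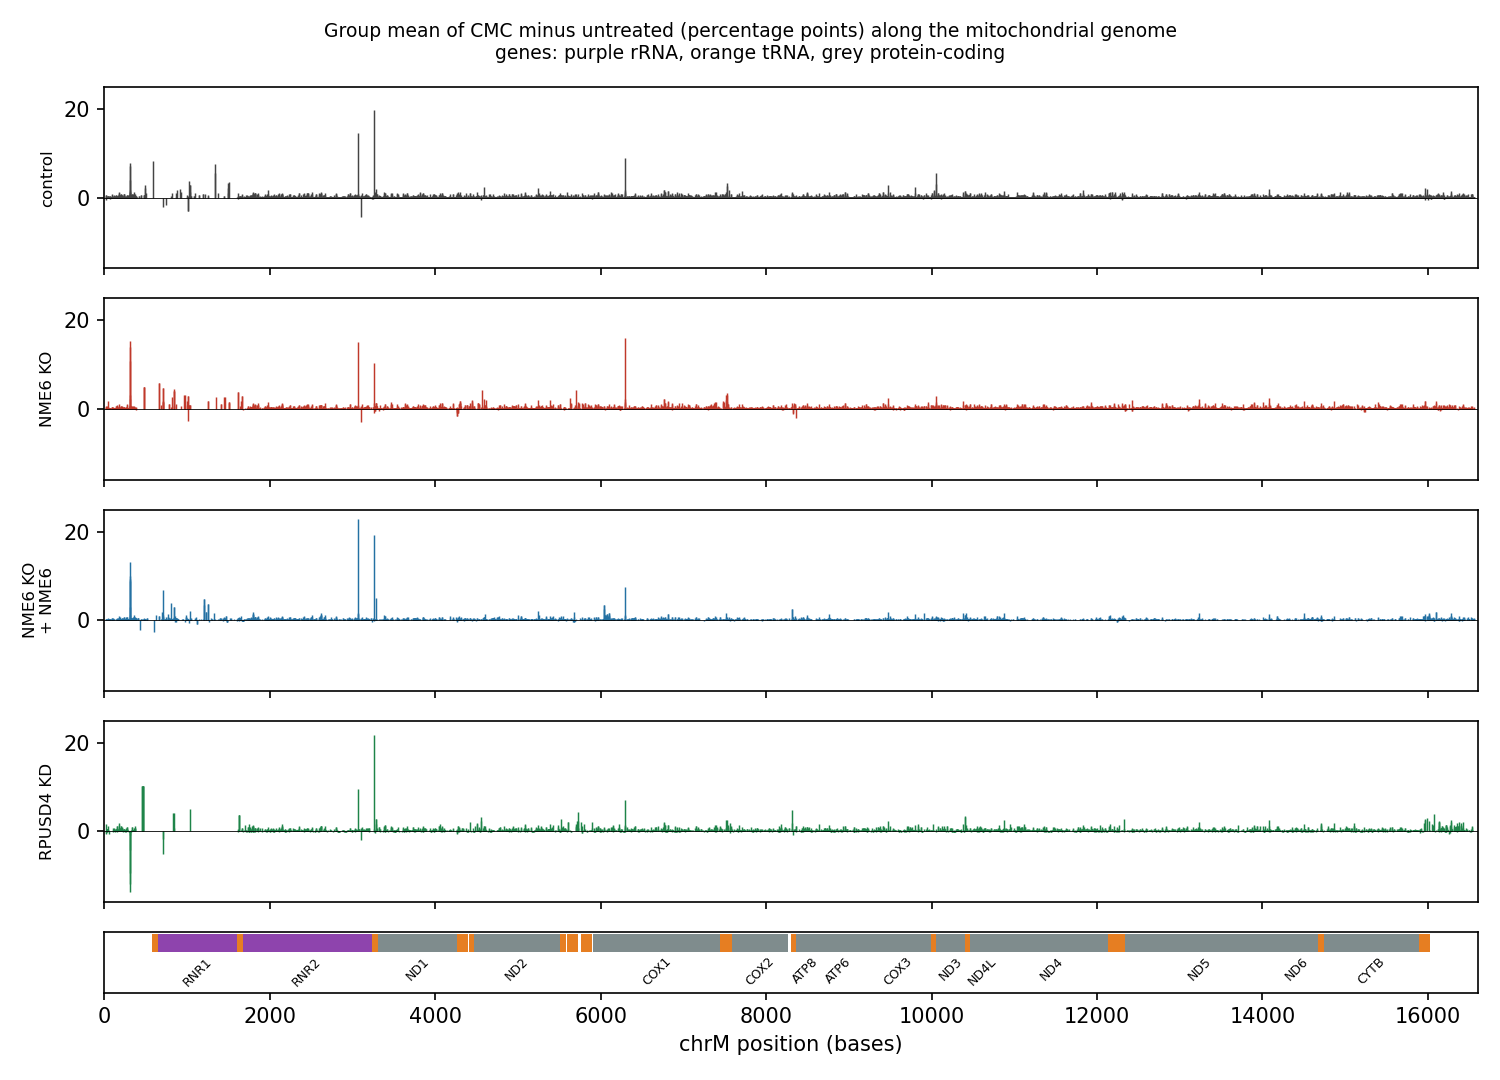
Group mean level (CMC minus untreated, percentage points, vertical axis) at each position of the mitochondrial genome (horizontal axis, bases) in the 4 groups of libraries, with genes drawn to scale below. The 16S rRNA position 3067, the tRNA-Leu(UUR) position 3258 and the COX1 position 6293 stand above the rest inside genes.

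The comparison of RPUSD4 knockdown with control cells asked which positions depend on this synthase. The 16S rRNA position 3067 fell in the knockdown to 9.59 ± 0.549 points (SD, n = 3), which was 65.5% of the control level. The 3 knockdown libraries lay between 9.25 and 10.2 points, below all 4 control libraries, which lay between 13.8 and 15.8 points. The difference was -5.06 points (SE 0.940, 95% interval -7.12 to -3.00; limma, Benjamini-Hochberg adjusted p = 0.0298). It was the only one of 149 tested positions past the threshold, and 13 had an unadjusted p under 0.05. A higher untreated level subtracted in the knockdown group cannot be told apart from a lower CMC level at position 3067. The labels list a single untreated library for that group. The tRNA-Leu(UUR) position 3258 had 21.8 ± 3.53 points in the knockdown (difference 2.10, limma Benjamini-Hochberg adjusted p = 0.846). The COX1 position 6293 had 7.12 ± 0.488 points (difference -1.88, limma Benjamini-Hochberg adjusted p = 0.894). The other reported RPUSD4 targets lie in tRNAs and could hardly be read: TRNF position 616 was listed at 0 in all 14 libraries. In TRNM (tRNA-Met), position 4447 was listed at 0 in 2 control libraries and in the 3 knockdown libraries, and the other control libraries read 0.0855 and 0.146 points. The mean of these 2 positions differed by -0.0290 points (exact permutation p = 0.571). Among 15 tested 16S rRNA positions 12 were higher and 3 lower, and only position 3067 passed the test, also when adjusted over the list alone. Of the 17 positions in 12S rRNA, 33 in tRNAs and 64 in mRNAs none passed, over all positions or adjusted over the list alone. The 12S rRNA could hardly be read: 97.5% of its values over the 14 libraries were exactly 0. The mean over its tested positions was 0 in knockdown replicates 1 and 2. Counts of 12S rRNA positions, here and below, thus say little about that RNA.

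At position 3067 the exact permutation p was 0.0571, the smallest that 4 against 3 libraries allow (after Benjamini-Hochberg adjustment 0.0714 over the 5 comparisons at this position and 0.229 over the 10 highest control positions). The call was lost without control replicate 2 (limma Benjamini-Hochberg adjusted p = 0.0835), control replicate 4 (0.122), knockdown replicate 1 (0.109) or knockdown replicate 3 (0.0577), and with only the 2 groups in the fit (0.720), a median filter (0.0603) or scaled libraries (0.563), while the difference stayed between -5.37 and -4.67 points over all 7 omissions. With only the 2 groups the difference was still -5.06 points, and the SE rose to 4.63 from 0.940. The group SDs at this position were 0.549 and 0.911 points, so that SE does not reflect its own spread. Without replicate 1 of control and NME6 knockout, which stood apart from their groups, 7 positions passed, 1 higher and 6 lower. Position 3067 was among the lower ones, and the others are not named here, so that count shows no wider dependence on RPUSD4. Larger gaps that did not pass in the main fit lay in the control region. Positions 308 and 309 read -11.8 ± 9.28 and -13.7 ± 10.1 points in the knockdown against 7.90 ± 10.3 and 7.23 ± 9.21 in control (exact permutation p = 0.114 at both).

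NME6 knockout cells were compared with control cells to ask whether loss of this kinase alters the modification profile. No position passed the test (limma, Benjamini-Hochberg, 0 of 149), and 7 had an unadjusted p under 0.05. The 16S rRNA position 3067 stood at 15.1 ± 1.81 points (SD, n = 4), a difference of 0.487 points (SE 0.870, 95% interval -1.42 to 2.40; limma Benjamini-Hochberg adjusted p = 0.988, exact permutation p = 0.686). The tRNA-Leu(UUR) position 3258 read 10.4 ± 3.60 points, 53.0% of the control level. That difference of -9.25 points (SE 2.33) did not pass (limma Benjamini-Hochberg adjusted p = 0.303, exact permutation p = 0.0571). The COX1 position 6293 read 16.05 ± 3.06 points, 178% of the control level, and all 4 knockout libraries lay above all 4 control libraries. That difference of 7.05 points (SE 2.43) did not pass either (limma Benjamini-Hochberg adjusted p = 0.703). Its exact permutation p was 0.0286, the smallest possible for 4 against 4, and after Benjamini-Hochberg adjustment 0.0952 over the 5 comparisons at this position and 0.286 over the 10 highest control positions. With libraries paired by number, all 4 pairs were higher at position 6293 and all 4 lower at position 3258, and the exact sign-flip permutation p was 0.125 at both, the smallest that 4 pairs allow. With the number as a block the limma Benjamini-Hochberg adjusted p was 0.719 at position 6293 and 0.572 at position 3258. TRNM position 4447 read 8.33 points in knockout replicate 1 and 0 in the other 3, so the mean of the RPUSD4 tRNA positions differed by 1.01 points (exact permutation p = 1). Without that library it differed by -0.0290 points. Tested mRNA positions were higher at 45 and lower at 19 of 64 (mean 1.67 ± 0.118 against 1.37 ± 0.286 points, exact permutation p = 0.0857, 0.514 after Benjamini-Hochberg adjustment over 30 list tests). Without control replicate 1 the mRNA difference was 0.151 points, against 0.293 with it. Among tested tRNA positions 18 were higher and 15 lower, among 16S rRNA positions 9 and 6, and among 12S rRNA positions 9 and 6. No member of any list passed when adjusted over the list alone.

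With only the 4 positions of mean level 5 or more tested, and no variance trend in that fit, positions 3258 and 6293 passed (limma Benjamini-Hochberg adjusted p = 0.00481 and 0.00452, ranges over all alternatives 0.00481 to 0.848 and 0.00452 to 1).

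**Figure D2:**
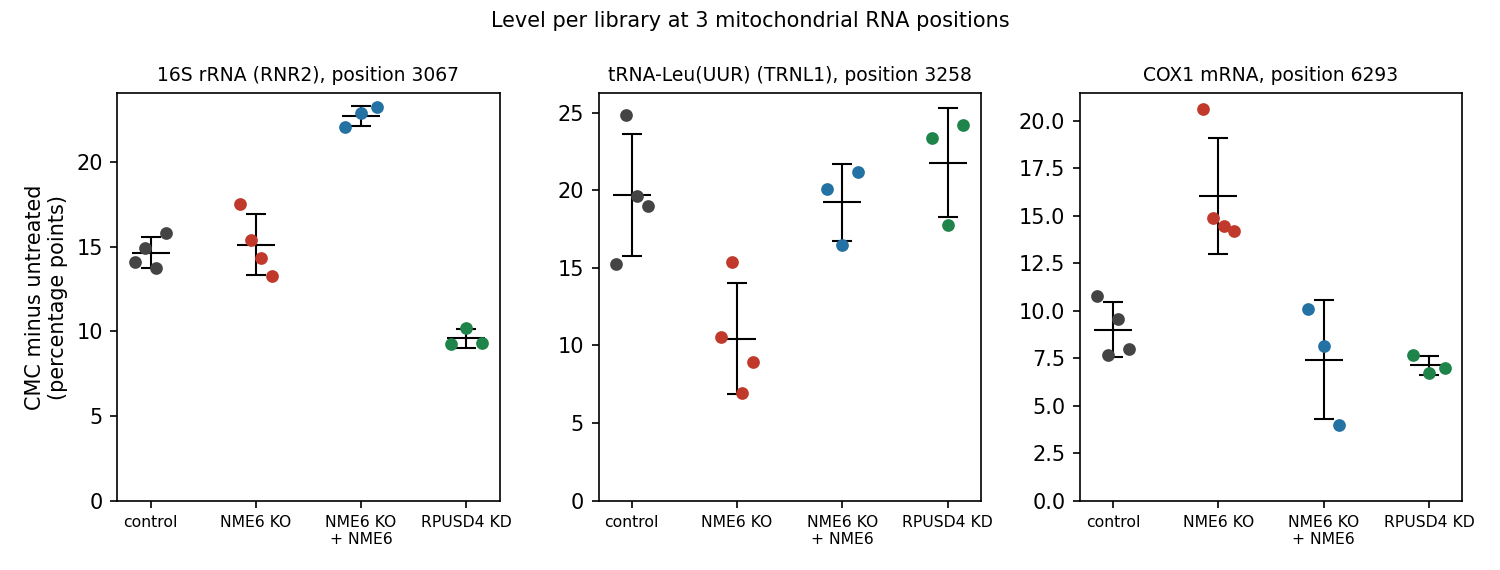
Level per library (points; CMC minus untreated, percentage points, vertical axis) by group at position 3067 of 16S rRNA, position 3258 of tRNA-Leu(UUR) and position 6293 of COX1, with group mean and SD (horizontal marks and bars; n = 4 control, 4 NME6 knockout, 3 rescued and 3 RPUSD4 knockdown libraries). The 16S rRNA level is lowest in the knockdown (9.59) and highest in rescued cells (22.8).

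Rescued cells were compared with the NME6 knockout they came from. The rescued samples appear to have been registered apart from the other groups, so a library batch cannot be told apart from the rescue. The 16S rRNA position 3067 rose from 15.1 ± 1.81 to 22.8 ± 0.599 points (n = 4 and 3), a difference of 7.63 points (SE 0.940, 95% interval 5.56 to 9.69; limma Benjamini-Hochberg adjusted p = 6.6e-04). Neighbouring positions 6043 and 6044, bases 140 and 141 of COX1, rose from 0.761 ± 0.176 and 0.556 ± 0.139 to 3.54 ± 0.836 and 3.38 ± 1.15 points (limma Benjamini-Hochberg adjusted p = 6.6e-04 and 0.00131). Further along the same mRNA, neighbouring positions 6762 and 6763 fell from 2.21 ± 0.305 and 2.32 ± 0.339 to 0.433 ± 0.0383 and 0.480 ± 0.0619 points (limma Benjamini-Hochberg adjusted p = 0.00538 for both). These 5 positions, 3 higher and 2 lower, were all that passed, and 23 had an unadjusted p under 0.05. The tRNA-Leu(UUR) position 3258 read 19.2 ± 2.47 points in rescued cells, and all 3 libraries lay above the 4 knockout libraries (difference 8.81, SE 2.52, limma Benjamini-Hochberg adjusted p = 0.0797). The COX1 position 6293 read 7.42 ± 3.12 points, with all 3 libraries below the knockout (difference -8.63, SE 2.63, limma Benjamini-Hochberg adjusted p = 0.0803). Tested mRNA positions were lower at 56 and higher at 8 of 64. Of these 4 passed over all positions and 10, of which 2 were higher, when adjusted over the list alone. The mRNA mean was 1.05 ± 0.113 against 1.67 ± 0.118 points (exact permutation p = 0.0571, the smallest possible, 0.429 after Benjamini-Hochberg adjustment). The mean over all 16570 positions moved the same way, 0.111 ± 0.0121 against 0.143 ± 0.0386 points (exact permutation p = 0.229). Among tested tRNA positions 21 were lower and 11 higher, and among 12S rRNA positions 9 and 8, with none past the test.

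Without rescued replicate 2 the count rose to 9, and without replicate 1 of control and knockout it rose to 22 (4 higher, 18 lower). With libraries scaled to their mean over untested positions 11 passed, 10 higher and 1 lower, against 3 and 2 unscaled, and positions 6762 and 6763 no longer passed (limma Benjamini-Hochberg adjusted p = 0.0798 and 0.0968), with differences of -1.66 and -1.71 points (SE 0.512 and 0.554) against -1.78 and -1.84 (SE 0.320 and 0.338) unscaled. With library weights 28 passed, 3 higher and 25 lower. All 4 COX1 calls were lost with no level filter (limma Benjamini-Hochberg adjusted p = 0.431, 0.111, 0.864 and 0.914 at positions 6043, 6044, 6762 and 6763), and that at 6044 with only the 2 groups in the fit (0.0525). With no level filter the 4 differences were unchanged. Only the SE rose, to 1.11, 0.696, 2.15 and 2.90 points from 0.366, 0.418, 0.320 and 0.338. With scaled libraries the difference at position 3067 was 15.4 points (limma Benjamini-Hochberg adjusted p = 0.0296). Position 3258 passed in 5 of 18 alternatives: without knockout replicate 2 (limma Benjamini-Hochberg adjusted p = 0.0333), with a mean level of 5 or more (0.00729), a median filter (0.0474), signed log2 (0.0333) or scaling (0.0206, difference 15.8 points). Position 6293 also passed in 5 of 18: with a mean level of 5 or more (8.6e-04), no variance trend (0.00861), positions outside genes left out (0.0194), signed log2 (0.0108) or library weights (0.0291).

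Set against control cells, rescued cells had a higher level at the 16S rRNA position 3067, 22.8 against 14.7 points, or 1.55-fold. The difference was 8.11 points (SE 0.940, 95% interval 6.05 to 10.2; limma Benjamini-Hochberg adjusted p = 3.8e-04), and the 3 rescued libraries, at 22.1 to 23.3 points, lay above all 4 control libraries. COX1 positions 6043 and 6044 were higher than in control, where they read 0.728 ± 0.219 and 0.498 ± 0.201 points (limma Benjamini-Hochberg adjusted p = 5.9e-04 and 0.00109). Position 7710, base 125 of COX2, another cytochrome c oxidase subunit, fell to 0.350 ± 0.0329 from 1.61 ± 0.532 points (limma Benjamini-Hochberg adjusted p = 0.0120). These were the 4 positions past the test, and 14 had an unadjusted p under 0.05. The tRNA-Leu(UUR) position 3258 differed from control by -0.449 points (SE 2.52, 95% interval -5.97 to 5.07) and the COX1 position 6293 by -1.58 points (SE 2.63, 95% interval -7.35 to 4.18). Those intervals are wide, so neither shows equal levels. Tested mRNA positions were lower at 57 and higher at 7 of 64. Of these 3 passed over all positions and 5 adjusted over the list alone. The mRNA mean differed by -0.322 points (exact permutation p = 0.171), while the mean over all positions was 0.111 against 0.140 points. The tRNA mean differed by -0.543 points (exact permutation p = 0.0571, 0.429 after Benjamini-Hochberg adjustment), with 23 positions lower and 10 higher and none past the test. Without control replicate 1, which read 33.3 points at TRNF position 588, the tRNA difference was -0.225 points.

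The COX2 call was lost without rescued replicate 1 (limma Benjamini-Hochberg adjusted p = 0.0737), 2 (0.0538) or 3 (0.0650), with only the 2 groups in the fit (0.117) and with no level filter (0.543). The difference stayed between -1.27 and -1.24 points in these fits, against -1.26 in the main one. Lost too were the calls at COX1 positions 6043 and 6044 with no level filter (limma Benjamini-Hochberg adjusted p = 0.573 and 0.144), the latter also with only the 2 groups in the fit (0.0557). With no level filter these 2 differences were unchanged, and their SE rose to 1.11 and 0.696 points from 0.366 and 0.418. Without replicate 1 of control and knockout 12 positions passed, 4 higher and 8 lower, and with library weights 29, 6 higher and 23 lower, against 3 and 1 unweighted. With scaled libraries the difference at position 3067 was 15.6 points (limma Benjamini-Hochberg adjusted p = 0.0450).

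NME6 knockout and RPUSD4 knockdown cells were compared directly. The 16S rRNA position 3067 was higher in the NME6 knockout by 5.54 points (SE 0.940, 95% interval 3.48 to 7.61; limma Benjamini-Hochberg adjusted p = 0.0135). The tRNA-Leu(UUR) position 3258 was lower in the NME6 knockout, at 10.4 ± 3.60 against 21.8 ± 3.53 points (difference -11.4, SE 2.52, limma Benjamini-Hochberg adjusted p = 0.0471). Neighbouring positions 10408 and 10409, bases 4 and 5 of TRNR (tRNA-Arg), were lower too, 0.880 ± 0.784 and 0.913 ± 0.804 against 3.41 ± 0.825 and 3.30 ± 0.485 points (limma Benjamini-Hochberg adjusted p = 0.0471). Control read 1.59 ± 0.894 and 1.61 ± 0.908 points at these neighbours. All knockdown libraries lay above all control libraries there, while knockout libraries overlapped control. At position 3258, by contrast, control (19.7 points) lay nearer the knockdown. Position 307 of the control region was higher in the NME6 knockout, 14.04 ± 10.3 against -9.40 ± 5.13 points (limma Benjamini-Hochberg adjusted p = 0.0471). These 5 passed of 149, and 14 had an unadjusted p under 0.05. Levels at position 307 were uneven: -1.34 to 19.5 points in the knockout, -15.1 to -5.29 in the knockdown and -9.44 to 6.25 in control. Whether that position is a uridine was not checked. Of 33 tested tRNA positions 3 passed over all positions and 5 adjusted over the list alone, all lower in the NME6 knockout. Positions 8316 and 15989, added by the list alone, read 0.0735 and 0 points in the knockout and 4.85 and 3.02 in the knockdown. Control lay between, at 1.06 and 0.706 points. Of 20 tested positions outside genes 1 passed and 4 adjusted over the list alone. The COX1 position 6293 differed by 8.93 points (SE 2.63, limma Benjamini-Hochberg adjusted p = 0.0776).

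This count hung on single libraries. It was 0 without NME6 knockout replicate 3 or RPUSD4 knockdown replicate 1, 1 without knockout replicate 4, 2 without knockout replicate 2 or knockdown replicate 3, 0 with libraries scaled to their mean over untested positions, and 0 with only the 2 groups in the fit (limma Benjamini-Hochberg adjusted p = 0.198 at 3067, 3258 and 10409, 0.199 at 307 and 10408). At position 3067 the adjusted p was 0.0590 and 0.0597 (limma, Benjamini-Hochberg) without those first 2 libraries, and at position 3258 the omissions gave 0.0225 to 0.162, and the call was lost in 5 of 7. Without knockout replicate 1 the count stayed 5, but all 5 were higher and positions 3258, 10408 and 10409 were lost (limma Benjamini-Hochberg adjusted p = 0.0566, 0.0574 and 0.0567). Position 10409 was lost in all 7 omissions (0.0535 to 0.162), 10408 in 6 (0.0494 to 0.162) and 307 in 6 (0.00821 to 0.231).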

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

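Tests chosen only after the results were seen were the regroupings of libraries with either way of counting, both comparisons of mean levels over untested positions and the check for shared untreated values. The zero share in TRNL1 and the replicate 1 correlation were predicted before their values were computed.

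The 16S rRNA position 3067 stood 1.55-fold above control in rescued cells. A stronger CMC reaction across the rescued libraries was checked by the mean over 5904 untested positions. It was 0.719 of control, and the highest rescued library (0.803 relative to all libraries) lay below 0.966, the lowest control library times 1.55. That mean cannot decide, because it does not follow the level at position 3067. Control replicate 1 had a relative mean of 0.622 (others 1.17 to 1.19) but read 14.1 points there (others 13.8 to 15.8). Positions 3258 and 6293 were not higher than control in rescued cells (19.2 against 19.7 and 7.42 against 9.001 points). A rise shared by all high positions was thus not seen. A lower untreated level subtracted in the rescued group cannot be told apart from a higher CMC level, because identical negative values in 18 same-group pairs are in line with 1 untreated profile per group, and the untreated values were not used separately here. An effect of the NME6 cDNA, of growing separate cells, or of preparing or sequencing these libraries apart may also account for it and was not tested. The rescued samples appear to have been registered apart from the other groups. These sources therefore cannot be told apart in any comparison with rescued cells.

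The tRNA-Leu(UUR) position 3258 read 0.530 of control in the NME6 knockout, without passing the test over 149 positions. A weaker CMC reaction across the knockout libraries was checked by the ratio of means over untested positions, 1.04, or 1.03 without replicate 1 of both groups. That ratio cannot decide, because the mean does not follow high positions. Knockout replicate 1 had a relative mean of 0.679 (others 1.16 to 1.27) but the highest knockout level at position 3067 (17.5 points). Positions 3067 and 6293 were not lower in the knockout than in control (15.1 against 14.7 and 16.05 against 9.001 points). A fall shared by all high positions was thus not seen. Sparser reads over the tRNA cannot be told apart: 85.3% of TRNL1 positions were listed at 0 in the knockout and 65.0% in control, 20.3 points more, but libraries overlapped (74.7% to 93.3% against 52.0% to 85.3%), and within groups no one order held: the lowest level was in the sparsest control library (15.3 points) but in the least sparse knockout library (6.93). Against it, the RPUSD4 knockdown libraries were as sparse (84.0% to 92.0%) and read 17.7 to 24.2 points, the sparsest of them highest, but a share of zeros is no read count and that group had another perturbation, so it stays open. A higher untreated level in the knockout group stays open for the reason given above (18 pairs), and a loss of the modification without NME6 may be the source and stays untested.

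Replicate 1 of control and of the NME6 knockout stood apart from their groups. A library batch shared by the pair would make their deviations alike inside genes too, and the correlation over 129 such positions was 0.129 (Spearman 0.102), above the bound of 0.1 set in advance. Its 95% interval, -0.0452 to 0.295, includes 0 and treats positions as independent, so this correlation alone is weak evidence. Over all 149 tested positions the correlation was 0.471. Both libraries also had a low mean over all positions, 0.0851 and 0.0850 points against 0.156 to 0.166 in the others of their groups. Both had the largest share of positions at 0 in their group (58.9% and 68.2%). A shared technical difference may thus be present, and its source was not tested. The labels give no batch, and no biological explanation was tested.

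In all, 21 values lay far from the other 3 libraries of their group by Dixon's test, in 50 groups of 4 libraries. Chance gives about 1 in 20, and neighbouring positions are not independent. Over all positions control replicate 1 averaged 0.0851 points (others 0.156 to 0.159) and knockout replicate 1 averaged 0.0850 (others 0.158 to 0.166). Control replicate 1 also had means over tested positions of 1.44 in 16S rRNA (others 2.11 to 2.24), 2.99 in tRNAs (1.67 to 1.76), 0.948 in mRNAs (1.48 to 1.55) and -1.21 outside genes (2.21 to 2.36). In the control region it read -9.44, -7.56, -6.57 and -3.80 points at positions 307, 308, 309 and 310, where the other control libraries were positive. Knockout replicate 1 read -1.34, -3.88 and -5.75 points at positions 307, 308 and 309, with the other knockout libraries positive. Single-library values in control replicate 1 were 33.3 at TRNF position 588 and 22.2 at RNR1 position 1334, with 0 in the others. At COX1 positions 6762 and 6763 it read 1.32 and 1.46 (others 1.81 to 1.86 and 1.87 to 1.93), and at TRNR positions 10408 and 10409 it read 0.249 at both (others 1.997 to 2.07 and 2.03 to 2.09). Knockout replicate 1 read 20.6 at COX1 position 6293 (others 14.2 to 14.9), and its mean over the RPUSD4 tRNA positions was 4.17 (others 0).

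Libraries were regrouped in all 35 ways for each comparison. For RPUSD4 knockdown against control 4 of 35 gave as many calls as the real 1 (highest other 1), so chance is not excluded for the count. For NME6 knockout against control the real count was 0 (highest other 0), which all 35 reach, those that part all pairs of numbers included. In the other comparisons only the real grouping reached its count: rescued against knockout (1 of 35, real 5, highest other 3), rescued against control (1 of 35, real 4, highest other 1) and NME6 knockout against RPUSD4 knockdown (1 of 35, real 5, highest other 4). With each run of adjacent positions counted once the real values were 3, 3 and 4, the highest others 1, 1 and 3, and again 1 of 35 reached them. That share, 1 of 35, is the smallest these groups allow and is not adjusted for the 5 comparisons. For NME6 knockout against RPUSD4 knockdown the margin was 1 and the count fell to 0 without either of 2 single libraries, so little rests on it.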

How the results depend on the processing

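Settings chosen after seeing the data are the median filter, joint omission of replicate 1, omission of positions outside genes, signed log2, scaling, library weights and no variance trend; the rest were planned. Counts are given for RPUSD4 knockdown against control, NME6 knockout against control, rescued against knockout, rescued against control, and NME6 knockout against RPUSD4 knockdown, in this order, against 1, 0, 5, 4 and 5. They were 36, 72, 156, 103 and 76 with no level filter (14928 positions), of which 19, 18, 111, 66 and 22 were higher. In that fit the SE at position 307 in NME6 knockout against RPUSD4 knockdown was 534 points, against 5.68, so little rests on those counts. With a mean of 5 or more the counts were 2, 2, 3, 1 and 4 (4 positions, which also drops the variance trend). They were 0, 0, 5, 4 and 0 with only the 2 groups compared, 0, 0, 5, 5 and 9 with a median of 1 or more, and 7, 0, 22, 12 and 8 without replicate 1 of control and knockout. Outside positions left out gave 1, 0, 8, 6 and 5, signed log2 1, 0, 11, 8 and 7, scaling 0, 0, 11, 5 and 0, and weights 6, 2, 28, 29 and 8 (higher 1, 2, 3, 6 and 6, against 0, 0, 3, 3 and 2). With the replicate block they were 0, 0, 6, 3 and 4. Except for NME6 knockout against control the numbers do not pair samples, so the lost RPUSD4 call (-5.17 points, limma Benjamini-Hochberg adjusted p = 0.161) is no weaker effect, nor are the calls lost at 307 and 3258 in NME6 knockout against RPUSD4 knockdown (0.104 each) and at COX2 7710 in rescued against control (0.0566). In those 4 comparisons no library of the first-named group whose number both share correlated best with its own number in the other. Omitting 1 replicate gave 0 to 2, 0 to 0, 5 to 9, 3 to 6 and 0 to 5.

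At 16S rRNA position 3067 the direction held for RPUSD4 knockdown against control in every setting run, with -5.37 to -4.67 over omissions. The call was lost with only the 2 groups (-5.06, SE 4.63 against 0.940), the replicate block (-5.17), the median filter (-5.06) and scaling (-6.18). For NME6 knockout against RPUSD4 knockdown it was lost with only the 2 groups (5.54) and scaling (6.35), and omissions gave 4.75 to 6.16. For NME6 knockout against control omissions gave -0.310 to 1.102, and joint omission of replicate 1 gave -0.496. Reading the next position gave -0.0151, -0.0071, 0.0121, 0.0050 and 0.0080 in the order above, all near 0. Adjusted p over alternatives ran from 0.00136 to 1 for RPUSD4 knockdown (limma, Benjamini-Hochberg). Rescued against control reversed at 3258 with scaling (6.45) and over omissions (-1.93 to 1.27), and at 6293 with scaling (0.0234) and over omissions (-2.93 to 0.128).

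Lists were tested only with no level filter and single omissions besides the planned setting, and none passed, but with 30 tests adjusted together none could. Signs turned with no level filter for 16S rRNA (-0.00085, -0.00207 and -0.00291 in NME6 knockout against control, rescued against knockout and rescued against control), 12S rRNA (0.00472, rescued against knockout), tRNAs (-0.0314, RPUSD4 knockdown against control; 0.00656, NME6 knockout against RPUSD4 knockdown) and mRNAs (-0.00085, NME6 knockout against RPUSD4 knockdown). Over omissions NME6 knockout against control ran from -0.114 to 0.233 in 16S rRNA, -0.320 to 0.193 in tRNAs, -0.377 to 1.66 in 12S rRNA and -0.0290 to 1.36 at RPUSD4 tRNA positions. RPUSD4 knockdown against control ran from -0.0289 to 0.173 in mRNAs and -3.09 to 2.42 outside genes. Rescued against knockout ran from -1.42 to 0.612 in 12S rRNA, -2.05 to 0.2498 outside genes and -1.29 to 0.103 at RPUSD4 tRNA positions. Rescued against control ran from -0.331 to 0.640 in 12S rRNA and -0.0290 to 0.126 at RPUSD4 tRNA positions. NME6 knockout against RPUSD4 knockdown ran from -0.455 to 5.06 outside genes and 0.0 to 1.39 at RPUSD4 tRNA positions. The cause of these changes was not tested. Not run, for lack of depth, counts, bases or separate untreated values: depth minimums, pseudocounts, uridines only, the quasi-binomial model, the untreated alternative, the list of tRNA positions 27 and 28, the list of other bases, and coverage per gene. Unknown depth limits every value.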

Other observations

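Some RNAs had few values other than 0, and the depth behind them is unknown. In the 12S rRNA gene RNR1 97.5% of values over the 14 libraries were exactly 0, against 22.5% in the 16S rRNA gene RNR2, 31.6% in COX1 and 26.9% in ND6. Among tRNA genes the share ran from 33.3% in TRNR to 99.5% in TRNF, where only 3 of 71 positions had a value other than 0 in any library. Position 9478, base 272 of COX3, a further cytochrome c oxidase subunit, was chosen after its values were seen. It read 1.63 to 3.14 points in the 14 libraries, with means of 2.75 ± 0.260 in control, 2.56 ± 0.430 in the NME6 knockout, 2.47 ± 0.399 in the RPUSD4 knockdown and 1.84 ± 0.282 in rescued cells. All 3 rescued libraries lay below the 4 control libraries (limma Benjamini-Hochberg adjusted p = 0.630).

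Calls came in adjacent pairs in COX1 and TRNR, and 80 of the 149 tested positions had a tested neighbour. As a hypothesis, 1 read event may span neighbouring bases, so that adjacent calls are not independent. The test was planned before its value was computed. Deviations from group means correlated across libraries with a median of 0.979 for 34 adjacent pairs inside genes, against 0.0097 for 474 other pairs in the same gene. This is in line with the hypothesis, under which the pairs 6043 and 6044, 6762 and 6763, and 10408 and 10409 would each count once.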
